A study of Mus musculus with 69 samples.

How the data were processed

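RNA was measured in 4 brain tissues of C57BL/6 mice (brain stem, frontal cortex, hippocampus and striatum) on 69 Illumina bead arrays, 1 tissue sample per array. Per the labels, the mice were wildtype or homozygous for the ENU-induced L100P mutation of Disc1, 10 to 12 weeks old, and received either valproate at 200 mg/kg or saline vehicle by intraperitoneal injection, 2 times a day for 15 days; tissue was collected on the day following the final dose. They formed a cohort apart from the animals used for behaviour. RNA was extracted with Trizol, cleaned on columns and amplified into biotin-labelled cRNA, per the labels' protocols. The 2 genotypes and 2 treatments gave 4 groups per tissue and 16 groups in all, with 3 to 6 arrays each, taken from the labels. The labels do not say that each array of a group came from a separate animal, nor whether arrays of different tissues share a mouse, so p-values measure the spread between these arrays.

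Both kinds of values deposited for these arrays were read. The deposited value table holds 25697 probes per array on a log2 scale; its scale was checked by setting each column against the bead-level file of the same array. All 69 columns matched their own bead-level file best, with a slope of table value on log2 bead intensity between 0.975 and 1.01 over the upper quantiles (median 0.996). R 2.8.1 is named in the submitters' processing notes, but the normalization behind the deposited log2 values is not given in the sources used here. Column medians differed between the tissues and lay at 6.02 to 6.22 in brain stem, 6.01 to 6.11 in frontal cortex, 6.30 to 6.39 in hippocampus and 5.71 to 5.87 in striatum, and levels are compared only within a tissue. The bead-level files hold 1 green fluorescence intensity per bead, per the file headers. A few values lie below 0 (at most 0.0271% of the beads of an array), so a local background had already been subtracted, by a method not given in the sources used here. Each array carried 965306 to 1071412 beads of 26821 types, with a median of 35 to 39 beads per type.

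The plan written before the data were examined took the bead-level intensities as the source of the main values, and the deposited value table in their place if bead types could not be named. The codes of the bead types pair with no gene in the tables used here, so the value table gave every named result. The bead-level intensities served to check the table and as an alternative for counts of called features. For that alternative, beads over 3 median absolute deviations from the median of their type were removed (0.878% to 3.07% per array), the rest averaged, means below 1 set to 1, and log2 values quantile normalized within each tissue. The platform annotation gave 1 gene symbol to 23978 probes, several to 0 and none to 1719; gene numbers of 23962 probes were found in the RefSeq gene table of assembly GRCm38.p6, which supplied current symbols. Because the deposited files name no genome build, gene positions are not printed, and that table was used only for names and for which genes neighbour each other. For the 4777 genes with more than 1 probe, the probe with the highest mean level over all arrays was tested. The 50% of the resulting 18312 genes and unnamed probes with the highest mean level in a tissue were kept, which left 9156 per tissue. Probes of histone genes, Hspa1a, Ifit3 and the Ccl21 genes have near-identical paralogs and may pick up more than 1 gene, so these names are uncertain.

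Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with 4 group means and no covariate. Valproate is the mean of the valproate-minus-vehicle differences of both genotypes, genotype is the mean of the mutant-minus-wildtype differences under both treatments, and interaction is the valproate difference in mutants minus that in wildtype mice. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a contrast were called. Changes are log2 fold changes ± the standard error (SE) of the moderated fit, group levels are means ± SD, and every adjusted p of a gene is limma's. Gene lists were fixed before the data were examined: 34 lists of pathways and cell types, each tested with camera in limma at a preset correlation of 0.01 where at least 5 genes were tested, with adjustment over all 384 combinations of list and contrast. Of the 75 combinations called, 6 were also called with the correlation estimated from the data: heat shock in brain stem and hippocampus, immediate early genes in frontal cortex, hippocampus and striatum, and the deacetylase-inhibitor induced list in striatum, all for valproate. The list adjusted p is camera's over these combinations, and a value given as estimated is the adjusted p with an estimated correlation. Members of a list were also adjusted over the list alone. Lists of striatal, hippocampal, cortical layer, hindbrain and choroid plexus markers were read on every array to check the tissue labels, and Eif2s3y and Xist to check the sex labels, after quantile normalization of all arrays together. Differences between tissues were tested for the named genes with limma's F-test in 1 fit over all arrays. NumPy 2.4.6 and Matplotlib 3.10.9 under Python 3.11.15 were used for bead summaries and plots.

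Genes named in the text follow a rule set at the same time as the lists. For valproate and genotype these are the 10 called genes with the largest positive and the 10 with the largest negative change, and for the interaction the 10 with the largest absolute change. Where no gene was called, the 3 with the smallest p are named as not called. Disc1 and Lcn2 are named in every tissue, as are up to 4 members with the smallest p of each list called. Genes of the genotype fit over all tissues and the histone genes counted beyond this rule were chosen after their values were seen.

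On simulated values drawn at the real means and spreads, with 200 of 9156 genes changed by 0.5 on the log2 scale, the valproate contrast recovered 85.5% in brain stem, 77.5% in frontal cortex, 85.5% in hippocampus and 54.0% in striatum. At a change of 1 it recovered 98.5%, 100%, 100% and 97.0%. The interaction recovered 1%, 0%, 0.5% and 0% at a change of 0.5, and 74.0%, 83.0%, 83.5% and 56.0% at a change of 1, and the genotype contrast 75.0%, 77.0%, 88.5% and 51.0% at 0.5. Camera found 12 of 12 shifted lists and 0 of the unshifted ones. The simulated genes were drawn independently and without slide differences, so this cannot show how camera treats lists of correlated genes. With 200 genes changed, the Benjamini-Hochberg cut-off is looser than where few genes change. Recovery in the real contrasts may therefore be lower, and few calls do not show that few genes changed by 0.5. For arrays, the number per group limits the precision of each value.

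Alternatives set in advance were the bead-level intensities (as they are, after normexp with an offset of 50, as medians of beads, or with median scaling), median scaling of the table, quantile normalization over all arrays, no filter, a stricter filter (the top 25%), every probe tested, slide as a random block, labelled sex as a covariate, the replicate number as a block, 1 fit over all arrays, single genotypes or treatments, an estimated correlation for lists, and leaving out each array in turn. Chosen after the data were seen were slide as a fixed block, the level of Eif2s3y as a covariate, lists with the replicate block, and fits without arrays whose markers stand apart. The arrays lay on 9 slides, and the arrays of a tissue on 7 to 9 of them. Because no slide held more than 5 arrays of a tissue, values within single slides are not given, and the slide block stands in for them. In brain stem 3 of 7 slides held more than 1 group, and wildtype vehicle replicates 1 and 2 lay alone on theirs. Brain stem values with slide as a fixed block therefore rest on replicate 3 for that group. In hippocampus no slide held both wildtype vehicle and wildtype valproate arrays. Of the valproate arrays there, only wildtype replicates 2 and 5 and mutant replicates 3 and 4 shared a slide with another group. Hippocampal values with slide as a fixed block rest on these for their groups. A planned test of called genotype genes near Disc1 by distance was not run, since no genotype gene was called in any tissue and positions are not used.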

Results

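Of the 69 arrays, 16 are from brain stem, 17 from frontal cortex, 19 from hippocampus and 17 from striatum. In the order wildtype vehicle, wildtype valproate, mutant vehicle and mutant valproate, the groups hold 3, 6, 4 and 3 arrays in brain stem and 3, 5, 4 and 5 in frontal cortex. They hold 5, 5, 5 and 4 in hippocampus, and 3, 5, 4 and 5 in striatum. In hippocampus and striatum 1 array each carries the marker levels of the other tissue. Without these, any 2 arrays of a tissue correlated at 0.948 or higher. On the hippocampal array labelled mutant valproate replicate 1 the striatal dopamine receptor gene Drd2 read 10.5. Its striatal markers averaged 10.99, against 7.65 to 8.01 on the other hippocampal arrays. On the striatal array labelled mutant valproate replicate 2, Drd2 read 6.53, the striatal markers averaged 7.82, against 10.47 to 11.18 on the other striatal arrays, and the hippocampal markers 8.22, against 6.76 to 7.16. Both stay in the fits under their labels, and values without them follow where they matter.

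**Figure D1:**
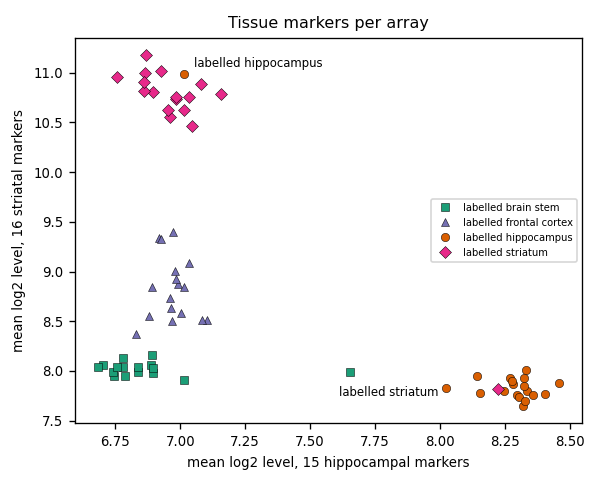
Mean log2 level of 15 hippocampal marker genes (x axis) and 16 striatal marker genes (y axis) on each of the 69 arrays, 1 point per array and 1 colour per tissue. The hippocampal array labelled mutant valproate replicate 1 (striatal markers 10.99) lies among the striatal arrays, and the striatal array labelled mutant valproate replicate 2 (striatal markers 7.82) among the hippocampal arrays.

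In frontal cortex valproate lowered activity-dependent genes. Egr2, a zinc-finger transcription factor induced by neuronal activity, fell by 1.22 ± 0.19 (log2, adjusted p = 0.0101). Its level went from 9.59 ± 0.34 to 8.24 ± 0.31 in wildtype mice (n = 3 and 5) and from 9.28 ± 0.38 to 8.19 ± 0.61 in mutants (n = 4 and 5). Arc, which acts in synaptic plasticity, fell by 0.94 ± 0.17 (adjusted p = 0.0259), the neurotrophin gene Bdnf by 0.56 ± 0.10 (0.0169) and the nuclear receptor gene Nr4a2 by 0.56 ± 0.11 (0.0421). Irs2, an adaptor of the insulin receptor, fell by 0.71 ± 0.11 (0.0101), and the transcription factor gene Nfil3 by 0.52 ± 0.09 (0.0148). The linker histone gene H1f2 fell by 0.53 ± 0.09 (0.0211) and the core histone gene H2bc6 by 0.61 ± 0.12 (0.0351). The cell-cycle inhibitor gene Cdkn1a decreased by 0.55 ± 0.09 (0.0101), and the chaperone genes Hspa1a and Dnajb1 by 0.77 ± 0.15 (0.0395) and 0.40 ± 0.08 (0.0421). Upward went Tmem40 (0.76 ± 0.11, adjusted p = 0.00812), Ly6g6e (0.86 ± 0.18, 0.0456), the galectin gene Lgals1 (0.65 ± 0.13, 0.0435) and the glutathione transferase gene Gstt3 (0.62 ± 0.12, 0.0351). So did the cold-inducible RNA-binding protein gene Cirbp (0.51 ± 0.10, 0.0456), the calcium sensor gene Hpcal1 (0.50 ± 0.10, 0.0351) and Art3 (0.45 ± 0.08, 0.0169).

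All 16 immediate early genes tested in frontal cortex were lower under valproate (median −0.49, 5 called, 14 when adjusted over the list alone; camera adjusted p = 3.49e-14, and 0.0457 with an estimated correlation). The list of genes induced by deacetylase inhibitors, a class to which valproate belongs, went down, with 8 of 13 lower. Its median was −0.09 and 4 were called lower, among them Cdkn1a, Bdnf and H1f2 (5 over the list alone; adjusted p = 0.00156, and 0.134 with an estimated correlation). The list shares Hspa1a and Hspa1b with the heat shock list, Hspa5 with the chaperone list and Bdnf with the immediate early list. With the glucocorticoid list it shares Cdkn1a, Mt1 and Mt2, so its changes in any tissue are not independent of those lists. Heat shock genes were lower in 10 of 15 (median −0.14, 2 called and 6 over the list alone; 0.00228, and 0.361 with an estimated correlation). Several lists were higher with no member called. Oxidative phosphorylation genes were higher in 47 of 49 (median 0.21; Ndufb5 0.56 ± 0.15, adjusted p = 0.102, list adjusted p = 6.25e-10, and 0.682 with an estimated correlation). Ribosomal protein genes were higher in 49 of 54 (median 0.21; Rps3a1 0.64 ± 0.17, 0.0973, list adjusted p = 3.79e-09, and 0.706 estimated). Interferon-response genes were higher in 13 of 14 (median 0.24; Oasl2 0.72 ± 0.19, 0.0992; 2 over the list alone, list adjusted p = 0.00202, and 0.706 with an estimated correlation). Among cell-type markers, astrocyte genes were higher in 13 of 17 (median 0.10; Glul 0.66 ± 0.16, 0.0911, list adjusted p = 0.0219, and 0.361 with an estimated correlation). Microglia genes were higher in 13 of 16 (median 0.17; P2ry12 0.48 ± 0.14, 0.119, list adjusted p = 0.0182, and 0.706 estimated), and meningeal genes in 9 of 9 (median 0.24, list adjusted p = 0.044, and 0.799 estimated). In each of these 3 lists 1 member passed over the list alone.

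In all, 23 genes were called for valproate in frontal cortex (7 higher, 16 lower), 1403 had an unadjusted p under 0.05, and 458 would be expected by chance. A fixed slide block brought the call count to 0. The immediate early list kept its shift (median −0.41, adjusted p = 2.16e-14) and 7 of the 9 lists stayed called, but not the interferon list (0.123) and meningeal markers (0.966, median −0.04). Omitting single arrays gave 7 to 29 genes, over 1.5 times more or fewer for 14 of 17 arrays. Quantile normalization over all arrays gave 15 (3 higher, 12 lower).

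**Figure D2:**
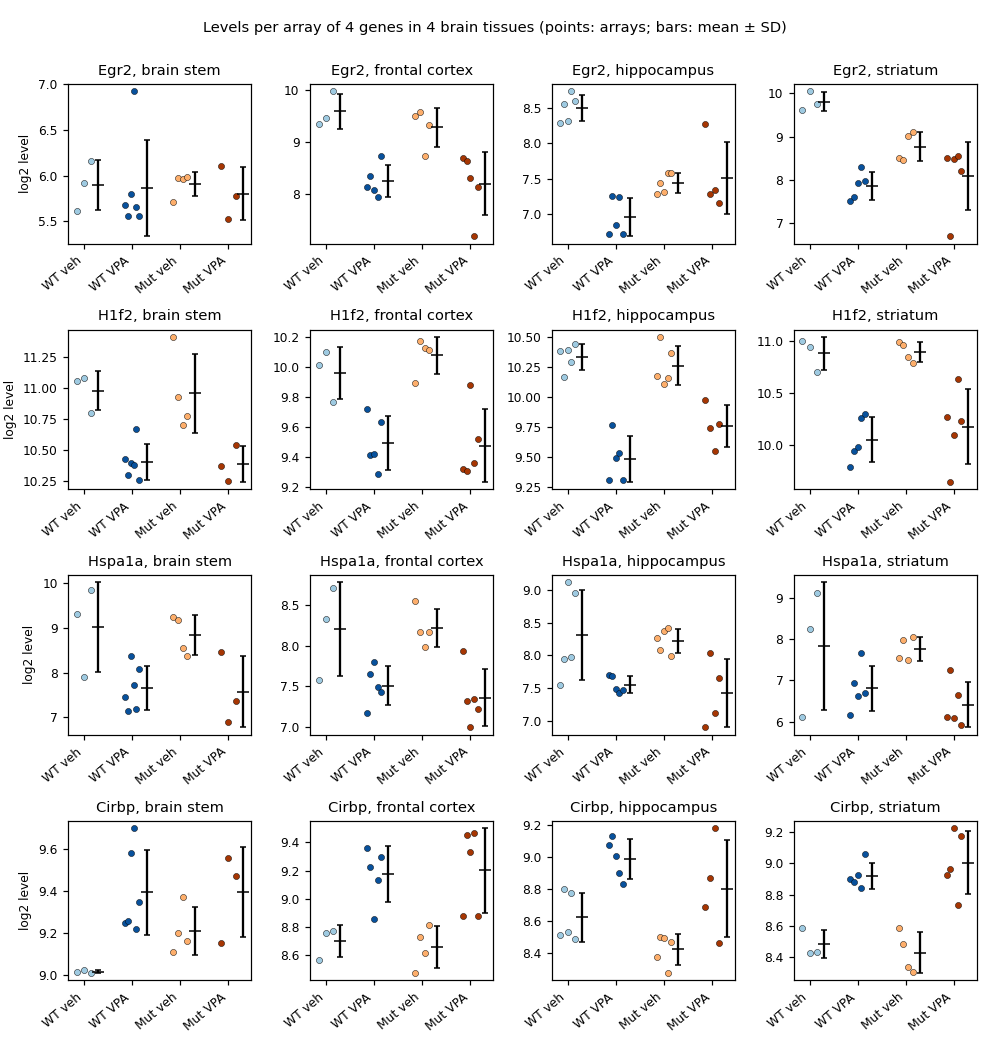
Log2 level (y axis, range set per panel) of Egr2, H1f2, Hspa1a and Cirbp in each of the 4 tissues, 1 point per array, by group (WT, wildtype; Mut, mutant; veh, vehicle; VPA, valproate). Egr2 fell by 1.22 in frontal cortex, 0.73 in hippocampus and 1.31 in striatum, H1f2 fell by 0.53, 0.67 and 0.77 in the same tissues, and Cirbp rose by 0.51 in frontal cortex and in striatum.

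In striatum valproate lowered Fosb, a subunit of the AP-1 transcription factor, by 1.07 ± 0.13 (adjusted p = 0.00158). Its level went from 8.90 ± 0.11 to 7.69 ± 0.39 in wildtype mice (n = 3 and 5) and from 8.18 ± 0.25 to 7.24 ± 0.17 in mutants (n = 4 and 5). Egr2 fell by 1.31 ± 0.22 (0.0297). Histone genes fell together: H1f2 by 0.77 ± 0.12 (0.0167), H2bc6 by 0.81 ± 0.15 (0.0432), H4c12 by 0.67 ± 0.12 (0.038), H3c4 by 0.62 ± 0.08 (0.00277) and H4c9 by 0.56 ± 0.10 (0.0332). Shisa2 fell by 0.88 ± 0.16 (0.0332), the phosphatase gene Dusp14 by 0.72 ± 0.14 (0.0432) and P4ha1, which hydroxylates collagen prolines, by 0.64 ± 0.12 (0.044). Cirbp rose by 0.51 ± 0.09 (0.0286) and Cstad by 0.54 ± 0.10 (0.0432).

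Immediate early genes in striatum were lower in 13 of 16 (median −0.32, 2 called and 7 over the list alone; Egr4 −0.66 ± 0.13, adjusted p = 0.066; Nptx2 −0.59 ± 0.14, 0.196, list adjusted p = 1.09e-12, and 0.0434 with an estimated correlation). All 15 heat shock genes were lower (median −0.29, 0 called and 9 over the list alone; Hspb1 −0.72 ± 0.15, 0.0879; Dnajb1 −0.39 ± 0.09, 0.182, list adjusted p = 1.93e-12, and 0.136 with an estimated correlation). Endoplasmic reticulum chaperones were lower in 13 of 16 (median −0.20; Creld2 −0.49 ± 0.10, 0.066, list adjusted p = 0.000128, and 0.288 estimated). The deacetylase-inhibitor induced list again went down, with 9 of 14 lower (median −0.21, H1f2 called, 5 over the list alone, list adjusted p = 0.000154, and 0.0457 with an estimated correlation). Interferon-response genes were higher in 11 of 14 (median 0.11; Ifit3 0.51 ± 0.11, 0.0688, list adjusted p = 0.0135, and 0.679 estimated), and glucocorticoid-induced genes lower in 14 of 18 (median −0.07, list adjusted p = 0.0244, and 0.706 estimated). Small rises covered oxidative phosphorylation genes, 40 of 49 (median 0.08, adjusted p = 0.0135, and 0.226 without the doubted array), and ribosomal protein genes, 45 of 54 (median 0.06, 0.0135, and 0.143 without it; 0.84 and 0.841 with an estimated correlation). Striatal markers, lower in 14 of 14 (median −0.46, 0.000631, and 0.758 with an estimated correlation), gave 0.0609 without the array labelled mutant valproate replicate 2.

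For valproate in striatum 14 genes were called (2 higher, 12 lower; 444 with an unadjusted p under 0.05). Without the array labelled mutant valproate replicate 2, 10 were called, 9 of them shared, and H4c12 (0.0501), Dusp14 (0.0517) and P4ha1 (0.0517) were not among them. A fixed slide block called 0 genes, yet 7 of the 9 lists stayed called and the immediate early list moved to −0.46 (adjusted p = 2.33e-27). The oxidative phosphorylation (0.363) and ribosomal lists (0.939, turned downward with a median of −0.00472) were lost. Fits lacking 1 array gave 2 to 18 genes, the fewest without wildtype vehicle replicate 2. It moved the count over 1.5 times for 12 of 17 arrays.

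In hippocampus the genes called lower under valproate were histone and immediate early genes. H1f2 fell by 0.67 ± 0.08 (adjusted p = 0.000359). Its level went from 10.33 ± 0.11 to 9.48 ± 0.19 in wildtype mice (n = 5 and 5) and from 10.26 ± 0.16 to 9.76 ± 0.17 in mutants (n = 5 and 4). H2bc6 fell by 0.71 ± 0.09 (0.00124), H4c8 by 0.58 ± 0.11 (0.0308), H3c6 by 0.52 ± 0.08 (0.0104) and H2ac18 by 0.37 ± 0.07 (0.0469). Egr2 decreased by 0.73 ± 0.13 (0.0162) and Arc by 0.63 ± 0.09 (0.0036). Upward went Pigz, a mannosyltransferase of the GPI anchor (0.82 ± 0.15, 0.0305), the keratin gene Krt12 (0.77 ± 0.15, 0.0469) and the interferon-induced gene Ifit3 (0.68 ± 0.13, 0.0308). Smaller rises were those of the circadian transcription factor gene Dbp (0.50 ± 0.10, 0.0457), Pitpnm3 (0.43 ± 0.09, 0.0478) and the RNA cap methyltransferase gene Pcif1 (0.35 ± 0.07, 0.0457). None of these 6 was called without the array labelled mutant valproate replicate 1 (adjusted p 0.057 for Pigz to 0.0739), and H2ac18 was not either (0.0739).

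Immediate early genes in hippocampus were lower in 15 of 16 (median −0.30, 2 called and 7 over the list alone; adjusted p = 3.17e-11, and 0.0313 with an estimated correlation). Heat shock genes were lower in 14 of 15 (median −0.27, 0 called and 9 over the list alone; Dnajb1 −0.37, 0.0659; Hspa1a −0.77 ± 0.18, 0.0885, list adjusted p = 4.57e-11, and 0.0434 estimated). Endoplasmic reticulum chaperones were lower in 14 of 16 (median −0.18; Xbp1 −0.28, 0.0965; Creld2 −0.33, 0.12, list adjusted p = 6.27e-06, and 0.17 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 18 (median −0.12; Mvd −0.28, 0.175, list adjusted p = 0.00228, and 0.272 estimated). The deacetylase-inhibitor induced list went down in 9 of 13 (median −0.09, H1f2 called, list adjusted p = 0.0061, and 0.266 with an estimated correlation). Interferon-response genes were higher in 12 of 12 (median 0.25, Ifit3 called and 7 over the list alone; Gbp3 0.35 ± 0.11, 0.18, list adjusted p = 3.18e-05, and 0.406 with an estimated correlation). Oligodendrocyte genes were higher in 14 of 14 (median 0.38, 0 called and 7 over the list alone; Mog 0.61 ± 0.17, 0.152; Opalin 0.58 ± 0.16, 0.158, list adjusted p = 3.97e-05, and 0.679 estimated). Striatal markers were higher in 12 of 12 (median 0.56; Drd1 0.90 ± 0.37, 0.308, and 0.39 without the doubted array, list adjusted p = 0.00369, and 0.792 with an estimated correlation). Their median was 0.03 in wildtype mice and 1.11 in mutants. The doubted array averaged 10.99 over these markers, against 7.93 to 8.01 on the other mutant valproate arrays. Hippocampal markers were lower in 9 of 11 (median −0.34; C1ql2 −1.03 ± 0.39, 0.268, and −0.51 without that array, list adjusted p = 0.00159, and 0.607 estimated).

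Valproate in hippocampus called 13 genes (6 higher, 7 lower; 1196 with an unadjusted p under 0.05), and 7 without the array labelled mutant valproate replicate 1 (1 higher, 6 lower, 6 shared). In a fit with slide fixed, where no slide held wildtype arrays of both treatments, 5 were called (3 shared). There 5 of 9 lists stayed called, among them immediate early (6.9e-10) and heat shock genes (2.73e-08), but not the interferon (0.112), cholesterol (0.521), striatal (0.917) and hippocampal (0.457) lists. Median scaling gave 2 higher and 7 lower, and quantile normalization over all arrays 3 and 7. Leaving out 1 array gave 4 (without mutant valproate replicate 3) to 59 genes (without mutant vehicle replicate 1), over 1.5 times off for 15 of 19 arrays.

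In brain stem 4 genes fell under valproate, 2 of them from the heat shock list. Cdkn1a fell by 0.79 ± 0.11 (adjusted p = 0.0157). Its level was 8.60 ± 0.44 and 8.40 ± 0.18 in wildtype mice on vehicle and valproate (n = 3 and 6) and 8.79 ± 0.09 and 7.42 ± 0.13 in mutants (n = 4 and 3). Tnfrsf12a, the receptor of the cytokine TWEAK, fell by 0.52 ± 0.08 (0.031), the small heat shock protein gene Cryab by 0.50 ± 0.08 (0.031) and Dnajb1 by 0.48 ± 0.08 (0.048). Heat shock genes were lower in 13 of 15 (median −0.25, 2 called and 10 over the list alone; Hspb1 −0.89 ± 0.17, 0.0693; Hspa1a −1.31 ± 0.29, 0.0939, list adjusted p = 2.96e-09, and 0.0457 with an estimated correlation). Endoplasmic reticulum chaperones were lower in 15 of 16 (median −0.19, 0 called and 6 over the list alone; Xbp1 −0.39 ± 0.08, 0.0939; Creld2 −0.30 ± 0.07, 0.106, list adjusted p = 4.67e-05, and 0.0872 estimated). Immediate early genes were lower in 12 of 15 (median −0.16, 0 called; Fos −0.76 ± 0.15, 0.0848, list adjusted p = 0.0149, and 0.741 with an estimated correlation). The deacetylase-inhibitor induced list went down in 10 of 14 (median −0.04, Cdkn1a called, list adjusted p = 0.0182, and 0.255 estimated). Oxidative phosphorylation genes were lower in 39 of 49 (median −0.10, list adjusted p = 0.00531, and 0.804 estimated), and genes of Wnt and GSK3 signalling higher in 13 of 15 (median 0.14, list adjusted p = 0.0118, and 0.271 estimated).

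Beside these 4 genes (0 higher, 4 lower), 1188 had an unadjusted p under 0.05 in brain stem. A fixed slide block gave 4 genes, 0 of them shared, and 4 of 6 lists stayed called (heat shock median −0.27, adjusted p = 6.6e-09), the oxidative phosphorylation (0.962) and Wnt lists (0.553) being lost. Omitting single arrays gave 0 genes without wildtype vehicle replicate 1 or mutant valproate replicate 2 and up to 141 without wildtype vehicle replicate 3, over 1.5 times off for 12 of 16 arrays. Quantile normalization over all arrays gave 1 higher and 4 lower.

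Lcn2, an iron-binding acute-phase protein, stood highest in vehicle-treated mutants in each tissue: 8.18 ± 0.90 in brain stem, 7.30 ± 0.76 in frontal cortex, 7.31 ± 0.82 in hippocampus and 6.93 ± 1.11 in striatum. In the same order, the other groups' means were 5.39 to 5.94, 5.38 to 6.37, 5.75 to 6.05 and 4.78 to 5.14. Tested without the level filter, it fell under valproate by 1.61 ± 0.28 in brain stem (adjusted p = 0.0457) and 1.45 ± 0.26 in frontal cortex (0.0279), with −0.82 ± 0.19 in hippocampus (0.113) and −1.25 ± 0.32 in striatum (0.412). Within mutants the change was −2.79 in brain stem (0.0117), −1.91 in frontal cortex (0.0793), −1.34 in hippocampus (0.0391) and −2.14 in striatum (0.203). Its interaction was not called in any tissue (−2.37, −0.92, −1.05 and −1.79; adjusted p 0.151, 0.927, 0.272 and 0.781).

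Among the named genes, the valproate change differed between tissues for 15 by limma's F-test. Except for Disc1 and Lcn2, they were named by their values in single tissues of these same arrays. This favours differences between tissues, so the adjusted p may be too small, and mice shared between tissues were not modelled. Shisa2 had the smallest adjusted p (2.55e-05), with −0.83 in striatum against 0.06, 0.04 and 0.02 in brain stem, frontal cortex and hippocampus. Arc (0.0265) changed by −0.05 in brain stem and by −0.93, −0.66 and −0.56 in the other 3 tissues in the same order. Egr2 (0.00252) changed by −1.21, −0.86 and −1.29 in those 3, and in brain stem, where it read 5.52 to 6.93 and did not pass the level filter, no fall can be read. Tmem40 (0.00252) changed by 0.73 in frontal cortex, the 1 tissue where it passed the level filter, and Irs2 (0.0256) by −0.70 there.

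Within single genotypes, valproate called 0 genes in wildtype brain stem (915 with an unadjusted p under 0.05) and 24 in mutants (6 higher, 18 lower). In frontal cortex it called 0 (1293) and 3, and in hippocampus 4 and 66 (51 higher, 15 lower). In striatum it called 0 and 0 (590 and 430), and 17 (8 higher, 9 lower) and 0 without the array labelled mutant valproate replicate 2. Egr2 fell by 1.54 in wildtype hippocampus (adjusted p = 0.000132) and changed by 0.07 in mutants, or by −0.18 without the array labelled mutant valproate replicate 1. No slide held wildtype hippocampal arrays of both treatments, so slide differences may be part of that fall. Cdkn1a fell by 1.37 in mutant brain stem (0.00152) and changed by −0.20 in wildtype mice. Without the array labelled mutant valproate replicate 1, mutant hippocampus gave 16 genes (10 shared).

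The negative interaction of genes induced by glucocorticoids was called as a list in each tissue at the preset correlation, and in none with an estimated one (adjusted p 0.271, 0.134, 0.361 and 0.0891 in brain stem, frontal cortex, hippocampus and striatum). Of its 18 genes, 17 were lower in brain stem (median −0.61, camera adjusted p = 1.27e-08). So were 16 of 18 in frontal cortex (−0.46, 3.86e-09), 16 of 18 in hippocampus (−0.49, 2.55e-05) and 16 of 18 in striatum (−0.70, 8.76e-12). No member was called over all genes, and 11, 6, 5 and 8 were lower when adjusted over the list alone. Sgk1, a kinase that regulates ion transport, had an interaction of −1.78 ± 0.45 in brain stem (adjusted p = 0.19), −0.91 ± 0.26 in frontal cortex (0.667) and −1.50 ± 0.33 in striatum (0.295). The lipid droplet gene Plin4 had −2.33 ± 0.48 (0.112), −1.47 ± 0.28 (0.115), −0.86 ± 0.26 (0.14) and −2.16 ± 0.57 (0.395) in brain stem, frontal cortex, hippocampus and striatum. Median changes of the list under valproate, which were not tested within a genotype, were 0.22, 0.19, 0.30 and 0.23 in wildtype mice and −0.43, −0.25, −0.18 and −0.43 in mutants. Mutants on vehicle stood above wildtype mice on vehicle by 0.24, 0.22, 0.22 and 0.28. In fits with slide fixed, the interaction of the list kept its size in frontal cortex (−0.55, 1.53e-11) and striatum (−0.89, 3.23e-15). It was not called in hippocampus (−0.29, 0.425), where no slide held wildtype arrays of both treatments. In brain stem it was −0.65, but there wildtype vehicle replicates 1 and 2 lay alone on their slide, so this rests on replicate 3.

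**Figure D3:**
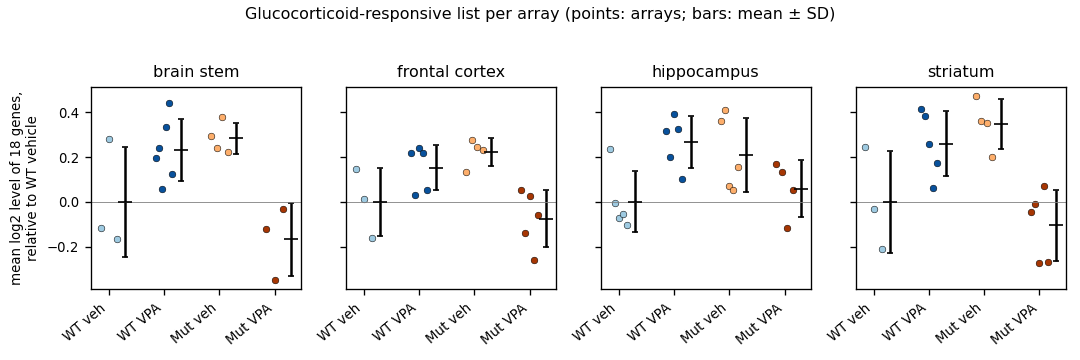
Mean log2 level of 18 glucocorticoid-induced genes on each array relative to the wildtype vehicle mean of its tissue (y axis), 1 point per array, by group in 4 tissues. In brain stem the group means were 0.23 for wildtype valproate, 0.28 for mutant vehicle and −0.17 for mutant valproate, and in striatum 0.26, 0.35 and −0.10.

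In hippocampus 10 genes had a called interaction. Egr2 had 1.61 ± 0.25 (adjusted p = 0.0216). Its means were 8.50 ± 0.19 on vehicle and 6.96 ± 0.27 on valproate in wildtype mice (n = 5 and 5) against 7.44 ± 0.14 and 7.52 ± 0.51 in mutants (n = 5 and 4). Dusp1, a phosphatase of MAP kinases, had 1.31 ± 0.22 (0.0256), Cdc42ep2 1.0 ± 0.18, the deubiquitinase gene Mindy1 0.85 ± 0.15 and the iron exporter gene Slc40a1 0.81 ± 0.15 (each 0.0256). Negative were Pglyrp1, a peptidoglycan recognition protein (−1.22 ± 0.22, 0.0256), Purb (−1.25 ± 0.24, 0.0412), the G protein gene Gna11 (−0.92 ± 0.18, 0.0356), the sorting adaptor gene Gga1 (−0.88 ± 0.15, 0.0256) and Upf1, a helicase of nonsense-mediated decay (−0.83 ± 0.15, 0.0256). Immediate early genes had a positive interaction in 11 of 16 (median 0.38, 2 called and 7 over the list alone; Arc 0.92 ± 0.19, 0.0569; Npas4 1.07 ± 0.22, 0.0686, list adjusted p = 0.0014, and 0.269 with an estimated correlation). Their medians under valproate were −0.49 in wildtype mice and −0.07 in mutants. Oligodendrocyte genes had a positive one in 13 of 14 (median 0.73, 0 called and 9 over the list alone; Mag 1.06 ± 0.29, 0.111; Opalin 1.06 ± 0.33, 0.14, list adjusted p = 9.79e-06, and 0.679 with an estimated correlation). Inflammation genes were negative in 7 of 8 (median −0.29; Osmr −0.51 ± 0.13, 0.1, list adjusted p = 0.0215, and 0.226 estimated). Astrocyte genes were negative in 13 of 17 (median −0.29; Gfap −1.13 ± 0.48, 0.254, list adjusted p = 0.0327, and 0.112 without the array labelled mutant valproate replicate 1). Ependymal genes, positive in 5 of 5 (median 0.37; 0.048), gave 0.27 without that array, and striatal markers, positive in 12 of 12 (median 1.02; 0.0063), gave 0.335. With an estimated correlation the adjusted p of these last 3 lists was 0.679, 0.703 and 0.799.

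The interaction in hippocampus had 5 genes higher and 5 lower (1491 with an unadjusted p under 0.05), and 25 without the array labelled mutant valproate replicate 1, all 10 shared (Egr2 1.36, adjusted p = 0.00363). A fixed slide block gave 219 genes, 2 of them shared, and 1 of 7 lists stayed called (astrocyte, 0.034; immediate early 0.849; oligodendrocyte 0.938; inflammation 0.48). That fit rests on wildtype valproate replicates 2 and 5 and mutant valproate replicates 3 and 4. Since no slide held wildtype arrays of both treatments, it cannot decide whether slides play a part in this interaction. Quantile normalization over all arrays gave 11 higher and 7 lower. Fits lacking 1 array gave 0 to 112 genes (the most without mutant vehicle replicate 1), with 0 for 5 of the 19 arrays and over 1.5 times off for 10.

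In brain stem Mrpl39, a protein of the mitochondrial ribosome, had an interaction of 1.5 ± 0.22 (adjusted p = 0.0314). Its means were 7.09 ± 0.19 and 6.28 ± 0.19 in wildtype mice on vehicle and valproate (n = 3 and 6) and 6.12 ± 0.33 and 6.81 ± 0.14 in mutants (n = 4 and 3). Cdkn1a had −1.17 ± 0.22 (0.084). Ribosomal protein genes had a negative interaction in 49 of 54 (median −0.30, 0 called; Rps6 −0.61 ± 0.16, 0.19, list adjusted p = 4.14e-07, and 0.706 with an estimated correlation, 4.69e-08 with slide as a fixed block). Beside the 1 called gene, 1235 had an unadjusted p under 0.05, and with slide as a fixed block 0 were called. Median scaling gave 11 genes (2 higher, 9 lower) with the median of all genes shifted by −0.15. Leaving out 1 array gave 0 to 241 (the most without wildtype vehicle replicate 3), over 1.5 times off for 12 of 16 arrays.

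Frontal cortex had 0 genes with an interaction called by limma (520 with an unadjusted p under 0.05). The 3 smallest p belonged to Tob1, a repressor of proliferation (0.98 ± 0.17, adjusted p = 0.11), the cadherin gene Cdh4 (0.84 ± 0.15, 0.115) and the homeobox gene Hhex (0.75 ± 0.14, 0.115). Tob1 had means of 8.90 and 8.37 in wildtype mice on vehicle and valproate and 8.38 and 8.84 in mutants. Microglia genes had a negative interaction in 14 of 16 (median −0.36; Ctss −0.99 ± 0.30, 0.721; Cx3cr1 went the other way, 0.68 ± 0.22, 0.721, list adjusted p = 0.00049, and 0.599 with an estimated correlation). Glutamate receptor genes had a positive one in 10 of 10 (median 0.34; Gria3 0.72 ± 0.26, 0.721, list adjusted p = 0.000892, and 0.361 estimated), and meningeal genes in 7 of 9 (median 0.46, list adjusted p = 0.0193, and 0.758 estimated). Endoplasmic reticulum chaperones were negative in 15 of 16 (median −0.20; Herpud1 −0.56 ± 0.15, 0.666, list adjusted p = 0.00131, and 0.365 with an estimated correlation). So were heat shock genes in 14 of 15 (−0.20; 0.00536, and 0.414 estimated) and fatty acid genes in 9 of 12 (−0.25; 0.0191, and 0.481 estimated). Oxidative phosphorylation genes were negative in 44 of 49 (−0.16; 0.000134, and 0.799 estimated) and ribosomal protein genes in 45 of 54 (−0.13; 0.00337, and 0.841 estimated). A fixed slide block called 0 genes and 4 of 9 lists, and lost meningeal (0.0895), glutamate receptor (0.0673), heat shock (0.099), fatty acid (0.0525) and oxidative phosphorylation genes (0.12). Omitting single arrays gave 0 genes throughout.

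Striatum had 0 genes with an interaction called by limma (466 with an unadjusted p under 0.05), and 59 without the array labelled mutant valproate replicate 2 (8 higher, 51 lower). The smallest p belonged to Id1, an inhibitor of bHLH transcription factors (−0.91 ± 0.17, adjusted p = 0.292, and 0.0311 without that array), the myosin light chain gene Myl4 (−2.99 ± 0.58, 0.292, and 0.029) and Arhgap25 (−1.49 ± 0.31, 0.292, and 0.0412). Slc17a7, a vesicular glutamate transporter, had −3.26 ± 0.92 (0.463, and 0.0311 without it) and the cortical transcription factor gene Tbr1 −2.74 ± 0.71 (0.395, and 0.0344). Cortical layer markers were lower in 6 of 11 (median −0.70, 3 over the list alone, list adjusted p = 0.0114, 0.163 with an estimated correlation and 0.0724 without that array). Their group means were 7.38 ± 0.30, 7.61 ± 0.09, 7.50 ± 0.06 and 7.33 ± 0.16 (n = 3, 5, 4 and 5). Mutant vehicle replicate 3 stood above its group in this list, with a gap of 0.93 of the group's range. Synaptic vesicle genes were lower in 15 of 17 (median −0.43, list adjusted p = 0.000183, and 0.679 with an estimated correlation). Choroid plexus genes were lower in 11 of 11 (median −1.62; Ttr −2.16 ± 0.80, 0.768, list adjusted p = 8.86e-07, and 0.679 estimated). Oligodendrocyte genes were higher in 14 of 15 (median 0.27; Opalin 0.71 ± 0.29, 0.83, list adjusted p = 0.00536, and 0.741 estimated). Immediate early genes were higher in 12 of 16 (median 0.28, mean 0.06; Junb 0.92 ± 0.22, 0.31, list adjusted p = 0.0442, 0.682 with an estimated correlation and 0.188 without that array). Slide as a fixed block called 0 genes and 3 of 6 lists, and lost immediate early (0.063) and cortical layer genes (0.0598). It turned oligodendrocyte genes downward (median −0.33, 0.216). Fits lacking 1 array gave 0 to 59 genes, over 1.5 times off for 3 of 17 arrays.

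Disc1 transcript levels were close to the floor of the arrays, with group means of 4.52 to 5.89. Their genotype change was −0.05 ± 0.10 in brain stem, −0.18 ± 0.10 in frontal cortex, 0.07 ± 0.06 in hippocampus and 0.06 ± 0.13 in striatum (adjusted p 0.939, 1, 0.814 and 0.978). Its probes measure the transcript and do not check the L100P change itself. For genotype, limma called 0 genes in each tissue. Of the tested genes, 718 in brain stem, 146 in frontal cortex, 908 in hippocampus and 718 in striatum had an unadjusted p under 0.05, where 458 would be expected by chance.

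In brain stem the smallest genotype p belonged to Mettl14, a subunit of the RNA adenosine methyltransferase (−2.65 ± 0.42, adjusted p = 0.0591). Its means were 8.86 ± 0.56 and 8.66 ± 0.53 in wildtype mice on vehicle and valproate (n = 3 and 6) and 6.89 ± 1.72 and 5.32 ± 0.03 in mutants (n = 4 and 3), and its other probe changed with the opposite sign. Lpcat1, an acyltransferase of phospholipids, had 0.45 ± 0.08 (0.087) and the peroxisomal transporter gene Abcd3 −1.0 ± 0.18 (0.101). Meningeal genes were lower in 9 of 9 (median −0.59, 3 over the list alone; Slc22a6 −1.09 ± 0.26, 0.201; Slc6a13 −0.94 ± 0.22, 0.182, list adjusted p = 3.68e-09, and 0.361 with an estimated correlation). Their group means were 7.74 ± 0.28, 7.48 ± 0.29, 7.26 ± 0.25 and 7.24 ± 0.20 (n = 3, 6, 4 and 3). Hippocampal markers were lower in 7 of 8 (median −0.21; Prox1 −0.39 ± 0.11, 0.302, list adjusted p = 0.0063, and 0.679 estimated). Their median was −0.10 between genotypes on vehicle and −0.31 on valproate, where wildtype valproate replicate 4 stood apart (7.65 against 6.90 for the next). Ependymal genes were higher in 7 of 8 (median 0.15, list adjusted p = 0.00802, and 0.641 estimated), and ribosomal protein genes in 40 of 54 (median 0.08, list adjusted p = 0.0253, and 0.846 estimated). A fixed slide block gave 7 genes, and all 4 lists stayed called (meningeal −0.36, adjusted p = 0.00502). Leaving out 1 array gave 0 to 9 genes (the most without wildtype valproate replicate 6), with a call for 4 of 16 arrays. Under valproate alone 7 genes were called between genotypes (3 higher, 4 lower), and 0 under vehicle (812 with an unadjusted p under 0.05).

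In frontal cortex Mmrn2, an endothelial matrix protein, had a genotype change of 0.53 ± 0.09 (adjusted p = 0.0891), the proteasome subunit gene Psmb5 −0.81 ± 0.14 (0.0891) and the RNA-binding protein gene Samd4 −0.92 ± 0.20 (0.637). Immediate early genes were lower in mutants in 12 of 16 (median −0.14, 0 called; Dusp1 −0.37 ± 0.13 and Junb −0.41 ± 0.15, both 1, list adjusted p = 0.000124, and 0.404 with an estimated correlation). Their median was −0.19 between genotypes on vehicle. Oxidative phosphorylation genes were lower in 38 of 49 (median −0.03, list adjusted p = 0.0491, and 0.888 estimated) and ribosomal protein genes in 37 of 54 (median −0.03, list adjusted p = 0.0327, and 0.888 with an estimated correlation, 0.156 with slide as a fixed block). Slide as a fixed block called 0 genes and kept 2 of 3 lists, and leaving out 1 array gave 0 to 1 genes.

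In hippocampus Camk1d, a calmodulin-dependent kinase, had a genotype change of 0.41 ± 0.08, the ribonuclease gene Rnase4 0.58 ± 0.11 and Samd4 −0.67 ± 0.13 (each with adjusted p = 0.0861). Markers of immature neurons were lower in 8 of 9 (median −0.15; Dpysl3 −0.40 ± 0.09, 0.138, list adjusted p = 0.0186, and 0.271 with an estimated correlation). Striatal markers were higher in 12 of 12 (median 0.47; Gng7 0.50 ± 0.20, 0.419, list adjusted p = 0.000144, 0.726 with an estimated correlation and 0.462 without the array labelled mutant valproate replicate 1). Oligodendrocyte genes were higher in 12 of 14 (median 0.14; adjusted p 0.014, 0.799 and 0.25 in the same order) and interferon-response genes in 9 of 12 (median 0.09; Irf9 0.27, 0.351, list adjusted p = 0.0206, 0.72 and 0.164). On vehicle alone 19 genes were called between genotypes (5 higher, 14 lower) and 0 under valproate (884 with an unadjusted p under 0.05). Without the array labelled mutant valproate replicate 1 the count on vehicle was 43 (10 higher, 33 lower). In a fit with slide fixed, 0 genes and 0 of 4 lists were called (immature neurons 0.146), and oligodendrocyte genes turned downward (median −0.04, 0.361). Omitting single arrays gave 0 to 37 genes (the most without wildtype vehicle replicate 1), with a call for 5 of 19 arrays.

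In striatum Dppa5a had a genotype change of 0.70 ± 0.13 (adjusted p = 0.336), the apolipoprotein gene Apoc1 0.55 ± 0.11 (0.371) and the transcription factor gene Nfic −0.61 ± 0.13 (0.371). Choroid plexus genes were higher in 11 of 11 (median 1.26, 0 called and 9 over the list alone; Kl 1.5 ± 0.45, 0.506; Folr1 1.26 ± 0.36, 0.506, list adjusted p = 2e-10, and 0.414 with an estimated correlation). Group means of this list were 6.91 ± 0.09, 7.80 ± 0.85, 8.57 ± 0.48 and 8.10 ± 1.08 (n = 3, 5, 4 and 5), and arrays within groups also differ in it. Meningeal genes were higher in 6 of 7 (median 0.41, list adjusted p = 0.00193, and 0.553 estimated), and oligodendrocyte precursor genes in 6 of 6 (median 0.16, list adjusted p = 0.044, 0.569 with an estimated correlation and 0.0609 without the array labelled mutant valproate replicate 2). Immediate early genes were lower in 13 of 16 (median −0.20, 2 over the list alone; Fosb −0.59 ± 0.13, 0.391; Junb −0.48 ± 0.11, 0.424, list adjusted p = 0.000124, and 0.271 estimated), with a median of −0.41 on vehicle. Disc1 and its interactors were lower in 18 of 23 (median −0.14; Pde4d −0.39 ± 0.17, 0.617, list adjusted p = 0.00805, and 0.159 with an estimated correlation). Oxidative phosphorylation genes were higher in 44 of 49 (median 0.09; 0.00797, 0.82 with an estimated correlation and 0.153 without that array) and ribosomal protein genes in 47 of 54 (median 0.08; 0.00579, 0.82 and 0.0722). Slide as a fixed block called 2 genes and turned the oxidative phosphorylation (−0.09, 0.0113) and ribosomal lists (−0.10, 0.00422) downward. It lost the meningeal (0.0986), precursor (0.12) and interactor lists (0.386) and kept the choroid plexus (1.98, 2.61e-11) and immediate early lists (−0.41, 2.23e-05). Fits lacking 1 array gave 0 to 1 genes.

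The genotype change differed between tissues for 10 of the named genes, with the same limits as for valproate. Igf2 (adjusted p = 9.02e-05) had −0.78 in brain stem and 0.88 in striatum, Lpcat1 (0.000806) 0.43 in brain stem and −0.31 in hippocampus, and Nfic (0.000905) −0.59 in striatum.

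Of the lists tested, 7 were called in no contrast. Their smallest adjusted p was 0.0666 for circadian clock genes, 0.0666 for endothelial and mural genes and 0.0963 for histone deacetylases. It was 0.148 for hindbrain and monoaminergic genes, 0.161 for GABA synthesis, transport and interneuron genes, 0.274 for inositol and protein kinase C genes and 0.456 for GABA-A receptor genes. The blood and erythroid list had fewer than 5 tested genes.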

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

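The tests in this part were chosen after the results were seen, except for the rules that picked out single arrays, the interaction genes and the differences between tissues. Of 533 groups of 4 to 6 arrays looked at, 35 had 1 array so far from its neighbour that the gap took up most of the group's range. Chance gives this in about 1 in 20 groups, or 27 here. Numbers below are the gap as a share of the range.

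On the hippocampal array labelled mutant valproate replicate 1, the striatal list (0.974), the choroid plexus list (0.872), Irf9 (0.947), the dopamine receptor gene Drd1 (0.928), Gng7 (0.863), the clock output gene Dbp (0.845) and Egr2 (0.832) stood above the rest of its group, and the hippocampal list (0.854), the dentate gyrus gene C1ql2 (0.889) and Gna11 (0.839) below it. On the striatal array labelled mutant valproate replicate 2 the striatal list (0.926) and Egr2 (0.809) were lowest and the hippocampal list (0.783) was highest. The hippocampal array correlated at 0.99 with the mean of striatum and 0.946 with the mean of hippocampus, and the striatal array at 0.984 with hippocampus and 0.953 with striatum. The 2 arrays both matched the other tissue best, which is what an exchange of the 2 samples would give. A mixture of tissues does not explain this, because on both of the 2 arrays the markers of the labelled tissue lay within the range of the other tissue, and an exchange of columns in the value table alone is excluded, because 2 of the 2 bead-level files also matched the other tissue. An exchange could have happened at any step up to scanning, no biological explanation was tested, and both arrays keep their labels.

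In brain stem the array wildtype valproate replicate 4 was highest for hippocampal markers (0.926, level 7.65 against 6.90 for the next) and cortical layer markers (0.883) and lowest for hindbrain markers (0.852). Mutant vehicle replicate 2 was highest for choroid plexus genes (0.881, level 8.28 against 6.82) and lowest for Cdkn1a (0.844), and mutant vehicle replicate 3 was lowest for cortical layer markers (0.849). Wildtype valproate replicate 2 was lowest for Creld2 (0.739) and highest for Tnfrsf12a (0.690). In frontal cortex mutant valproate replicate 4 was highest for Cdh4 (0.856) and lowest for Junb (0.818), replicate 3 highest for Ctss (0.883) and replicate 5 lowest for P2ry12 (0.792) in the same group, mutant vehicle replicate 4 lowest for Tob1 (0.841), and wildtype valproate replicate 4 lowest for hindbrain markers (0.786).

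Hippocampal mutant vehicle replicate 1 was highest for Reln (0.846) and lowest for Gng7 (0.718), mutant vehicle replicate 2 highest for Pglyrp1 (0.743), and mutant valproate replicate 3 lowest for Tsc22d3 (0.834). In striatum mutant vehicle replicate 3 was highest for Lcn2 (0.914) and cortical layer markers (0.930) and lowest for P4ha1 (0.846), and mutant valproate replicate 4 highest for H4c9 (0.841).

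The response to valproate differed between the genotypes by limma's interaction test for Mrpl39 in brain stem (adjusted p = 0.0314) and in hippocampus for Egr2 (0.0216), Dusp1, Cdc42ep2, Mindy1, Slc40a1, Pglyrp1, Gga1 and Upf1 (0.0256 each), Gna11 (0.0356) and Purb (0.0412). Differences of the valproate change between tissues passed limma's F-test for Shisa2 (2.55e-05), Egr2, Reln and Tmem40 (0.00252 each), Dusp14 (0.00390), Nfil3 (0.0122), Fosb (0.0137), Nptx2 (0.0175), Pitpnm3 (0.0205), Disc1 (0.0250), Art3 and Irs2 (0.0256 each), C1ql2 (0.0258), Arc (0.0265) and Dbp (0.0304). Reln, which marks Cajal-Retzius cells and interneurons, changed by 0.52 in hippocampus against 0.27, −0.02 and −0.15 in brain stem, frontal cortex and striatum, Nfil3 by −0.52 and −0.44 in frontal cortex and hippocampus against −0.13 and −0.03, and Disc1 by 0.09, 0.23, −0.03 and −0.23 at levels near the floor. Without the 2 doubted arrays Dbp was no longer called (0.105). The genes of this test and of that for genotype were mostly named from the same arrays, which favours differences between tissues. Egr2 in brain stem, C1ql2 in frontal cortex, Tmem40 outside frontal cortex and Disc1 throughout did not pass the level filter, so an absent change shows nothing there.

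Differences of the genotype change between tissues passed for Igf2 (9.02e-05), Lpcat1 (0.000806), Nfic (0.000905), Folr1 (0.00697), Apoc1, Camk1d, Dpysl3, Fosb and Kl (0.0129 each) and Slc22a6 (0.0327, and 0.0541 with slide in the fit). Folr1 and Kl, which are abundant in choroid plexus, had their largest value in striatum (1.15 and 1.41), and Slc22a6, a meningeal transporter, had −0.98 in brain stem. Folr1 passed the level filter in striatum alone, Apoc1 and Kl in all but frontal cortex and Slc22a6 in all but striatum.

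The negative interaction of glucocorticoid-induced genes in all 4 tissues, called at the preset correlation and in 0 tissues with an estimated one (adjusted p 0.271, 0.134, 0.361 and 0.0891), was set against 3 technical explanations. With slide as a fixed block the list was still called lower in 3 of 4 tissues, brain stem, frontal cortex and striatum. In brain stem that fit rests on wildtype vehicle replicate 3, since replicates 1 and 2 lay alone on their slide. With the level of Eif2s3y, a gene of male cells, as a covariate the list was called lower in 4. At the preset correlation this counts against slides in frontal cortex and striatum, and against sex, as the whole cause. Some of these genes are abundant in vessels, but in 4 of 4 tissues the median of the endothelial and mural list (0.05, −0.03, −0.05 and −0.08) fell short of that of the glucocorticoid-induced genes by more than the SD of its members. With slide as a fixed block this held in 3, narrowly in striatum (0.587 against an SD of 0.583), and not in hippocampus (0.203 against 0.647). This counts against a smaller share of vascular cells as the whole cause. In that fit the endothelial and mural list was itself called lower in striatum (median −0.30, adjusted p = 0.0113), so a part played by these cells there stays open. A response of mutants to valproate that differs from that of wildtype mice stays open and was not tested apart from these. Whether arrays of the 4 tissues came from the same mice is not given in the labels, so the tissues may repeat 1 observation.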

How the results depend on the processing

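Fits with slide as a fixed block, the level of Eif2s3y, without the arrays whose markers stand apart and without the choroid-plexus-high or hippocampal-marker-high array, and gene lists with the replicate block, were chosen after the results were seen; the others were planned. Except where a cause is given, the cause was not tested. Counts below are called genes, beside the values with the settings used throughout: valproate 4, 23, 13 and 14 in brain stem, frontal cortex, hippocampus and striatum, genotype 0 in each, and interaction 1, 0, 10 and 0.

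The splits of the arrays were planned too. Among 100 splits by drug within genotype, 2 gave at least as many valproate genes as the real one in brain stem (4, highest other 181), 2 in frontal cortex (23, highest other 590), 2 in hippocampus (13, highest other 174) and 1 in striatum (14, highest other 4), each counting the real split, so chance can be excluded at 0.05 for the count. All splits here ignore the slide, so differences between slides are not excluded by them. Counted at an unadjusted p under 0.05 instead, 34 of 100 splits reached the real 444 in striatum and 5 the real 1188 in brain stem, so for that count chance cannot be excluded there. For the interaction the count was 2 in hippocampus (10, highest other 70) and 9 in brain stem (1, highest other 49). In brain stem chance cannot be excluded, although only 3 splits reached its 1235 genes with an unadjusted p under 0.05. These splits also remove the valproate change that both genotypes share. A low count, as in hippocampus, therefore does not exclude chance for the interaction itself. Where the real count was 0 all 100 splits reach it by construction, which decides nothing: the interaction in frontal cortex (highest other 955) and striatum (183), and genotype in brain stem (151), frontal cortex (42), hippocampus (49) and striatum (58). Counted at an unadjusted p under 0.05, 34, 24, 19, 91, 10 and 19 splits were as large in the same order, so chance cannot be excluded for these. The median of the other splits was 0 throughout. Where genes were called, single splits with several times the real count, in all but striatal valproate, point to a structure among the arrays besides drug and genotype, which was not itself tested.

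The bead-level intensities, with bead types unnamed, gave for valproate 16 in brain stem and 6 in striatum, with 17 and 18 in frontal cortex and hippocampus, 1 for genotype in striatum, and for the interaction 0 in brain stem and 19 in hippocampus. After normexp they gave 14, 14 and 7 for valproate in brain stem, frontal cortex and striatum, 1 for genotype in striatum and 19 for the interaction in hippocampus. As medians of beads they gave 8, 14 and 9 for valproate in the same tissues, and 0, 1 and 16 for the interaction in brain stem, frontal cortex and hippocampus. With median scaling they gave 28, 5 and 9 for valproate, 5 for genotype in brain stem, and 0 and 78 for the interaction in brain stem and hippocampus.

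Median scaling of the table gave 7, 1 and 11 for valproate, genotype and interaction in brain stem. Quantile normalization over all arrays gave 15 for valproate in frontal cortex and 0 and 18 for the interaction in brain stem and hippocampus. Without a filter, more genes were tested, with 9 and 5 for valproate in brain stem and striatum and 1 for genotype in brain stem. The stricter filter tested fewer genes and gave 15, 2 and 9 for valproate in frontal cortex, hippocampus and striatum and 4 for the interaction in brain stem. With every probe tested the counts were 11, 10 and 7 for valproate in brain stem, frontal cortex and striatum and 2 for the interaction in brain stem.

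With slide as a random block valproate gave 8 in hippocampus, genotype 2 in frontal cortex and 19 in hippocampus, and the interaction 0 in brain stem. With slide as a fixed block, which also spends degrees of freedom, valproate gave 4 in brain stem with 0 shared, 0 in frontal cortex, 5 in hippocampus and 0 in striatum, genotype 7 in brain stem and 2 in striatum, and the interaction 0 in brain stem and 219 in hippocampus. Disc1 in hippocampus reversed there, from a genotype change of 0.07 to −0.01 (the unrounded value is −0.0141). Labelled sex as a covariate gave 1 and 8 for valproate in brain stem and striatum, 3 for genotype in frontal cortex, and 0, 6 and 1 for the interaction in brain stem, hippocampus and striatum. The level of Eif2s3y gave 7 and 8 for valproate in hippocampus and striatum, 2 and 1 for genotype in brain stem and hippocampus, and 0 for the interaction in brain stem.

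Replicate numbers did not clearly pair the arrays of a tissue. After removal of group means, arrays with the same number correlated on average at 0.042, 0.0449, 0.0505 and 0.0111. Other pairs averaged slightly lower, at −0.0095, −0.012, −0.0122 and −0.0047, and single same-number pairs ranged from −0.486 to 0.519. Whether a number shared between tissues marks the same mouse was not tested. As a block the number gave 0, 14 and 6 for valproate in brain stem, frontal cortex and striatum, 6 for genotype in brain stem, and 0 for the interaction in brain stem and hippocampus. A fit over all 69 arrays, with its pooled spread, gave 15, 44 and 39 for valproate in brain stem, hippocampus and striatum (32 in frontal cortex), 15 and 46 for genotype in brain stem and striatum, and 4, 2, 26 and 68 for the interaction in the 4 tissues.

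With fewer arrays, wildtype mice alone gave 0, 0, 4 and 0 genes for valproate and mutants alone 24, 3, 66 and 0. Without the 2 doubted arrays wildtype striatum gave 17, mutant hippocampus 16, and genotype on vehicle in hippocampus 43. Genotype gave 19 in hippocampus on vehicle alone and 7 in brain stem on valproate alone. Without the arrays whose markers stand apart, valproate and interaction gave 7 and 25 in hippocampus and the interaction 59 in striatum. Without the choroid-plexus-high brain stem array, valproate gave 1 and genotype 4, and without the hippocampal-marker-high one every count stayed within 1.5 times. Leaving out 1 array at a time gave for valproate 0 to 141, 7 to 29, 4 to 59 and 2 to 18 genes in the 4 tissues, for genotype 0 to 9, 0 to 1, 0 to 37 and 0 to 1, and for the interaction 0 to 241, 0 to 0, 0 to 112 and 0 to 59.

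Of the 171 results for named genes, most kept direction and side of the threshold: 154 with median scaling, 158 with quantile normalization over all arrays, 152 with slide as a random block, 150 with labelled sex, 152 with Eif2s3y and 116 with slide as a fixed block, where 54 were weaker. Labelled sex disagreed with Eif2s3y on 43 of 69 arrays, so for genes and lists alike that setting says little about sex. In leaving out 1 array, 2446 values kept them, 70 were stronger and 473 weaker. Many of the 171 results were not called at the outset, so keeping their side of the threshold does not test a call. In brain stem, frontal cortex, hippocampus and striatum, slide as a fixed block kept 0, 0, 3 and 0 of the valproate calls. Of the interaction calls it kept 0 in brain stem and 2 in hippocampus. Of the 75 calls of gene lists, an estimated correlation kept 6, slide as a fixed block 41 with 2 in the opposite direction, slide as a random block 69, labelled sex 72, Eif2s3y 70, the replicate block 67 and the fits without the 2 doubted arrays 61. That last count includes all calls in brain stem and frontal cortex, which hold no doubted array and were not refitted. The differences between tissues, 15 for valproate and 10 for genotype, were 15 and 9 with slide in the fit and 16 and 12 without the 2 doubted arrays.

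For arrays, signal over background limits genes such as Disc1, whose levels lie near the floor, and Egr2 in brain stem. The few arrays per group limit the interaction most: a change of 0.5 was recovered for at most 1% of simulated genes. For valproate and genotype 51.0% to 88.5% were recovered at that change.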

Other observations

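Replication-dependent histone genes were lower under valproate as a family in hippocampus, striatum and brain stem. The tests in this part were all chosen after the results were seen. In hippocampus 5 of the 7 called genes that were lower, and in striatum 6 of 12, are histone genes, in frontal cortex 2 of 16 and in brain stem 0 of 4. Lower were 19 of 28 tested histone genes in hippocampus (median −0.28), 28 of 31 in striatum (−0.40), 17 of 28 in frontal cortex (−0.05) and 25 of 29 in brain stem (−0.34). Camera with an estimated correlation gave p = 0.0343, 0.00124, 0.599 and 0.0313 in the same order. This family test was run with the doubted arrays kept and without a slide block, so slide differences are not excluded. Histone transcripts peak in dividing cells. The immature neuron and proliferation list was lower at an unadjusted p under 0.05 in 0 of these tissues, but only 3 cell-cycle genes were tested in each, so fewer dividing cells stay open. Because many of these transcripts differ little from each other, a probe may read several of them, which was not tested.

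Genes that differ between the genotypes lie beside each other. In 1 fit of the genotype change over all 4 tissues, 32 of 8560 genes were called (15 higher, 17 lower). Signs were counted for the 31 called genes with a name and a position, and all had the same sign in each tissue. The genes were called on the mean of these same 4 tissues, which favours equal signs, so this is no independent repeat. The strongest was Mettl14 (−2.13 ± 0.25, adjusted p = 9.08e-08), with Abcd3 (−0.84), Rwdd3 (0.48) and Gclm (−0.30), which makes a subunit of glutathione synthesis, within a span of 10 tested genes in assembly GRCm38.p6. Another block of 10 called genes among 32 tested ones holds Samd4 (−0.75 ± 0.10), Psmb5 (−0.70), the ribonuclease genes Ang (−0.59) and Rnase4 (0.48), the repair gene Apex1 (−0.54), Tmem260 (−0.49), Mettl17 (0.39), Abhd4 (−0.28), the methyltransferase gene Mettl3 (−0.22) and the chromatin remodeller gene Chd8 (0.20). Il17d (−1.50) lies near Adcy4 (−0.19), Esd (−0.73) near Rb1 (0.31), and Ccl21a (1.61) near its paralog Ccl21b (1.23). Arrays of different tissues may come from the same mouse, which would make these p-values too small. Of 10000 random sets of 31 genes with a name and a position, 0 had as many genes with a called neighbour (20 observed, median 2, highest 12). But these sets do not model mice shared between tissues.

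The blocks do not surround Disc1. Of the 108 tested genes nearest to Disc1, 0 were called, which counts against a segment that came along with the mutation as the source of these genes. Of called genes with another probe in the upper 50% by level, 62.5% (5 of 8) changed the same way there and Apex1, Il17d and Esd did not. Mettl14 is not among the 8, and its other, dimmer probe changed with the opposite sign in brain stem. Tnip1, Mettl17, Rb1, Gnpda1 and Rwdd3 changed the same way (Rwdd3 0.48 and 0.42, Mettl17 0.39 and 0.20). For these 5 this argues against a strain variant under 1 probe. Esd (−0.73) changed by −0.06, 0.03 and 0.04 at its other probes, Il17d (−1.50) by −0.01 and Apex1 (−0.54) by 0.10. The changes of Esd, Il17d and Apex1 thus belong to 1 probe each. For them and for genes without another bright probe, a variant under the probe cannot be told apart from a change in level. Mettl14 ranged from 4.05 to 8.41 on mutant arrays and from 7.63 to 9.27 on wildtype arrays, so the mutants were not uniform. Segments elsewhere in the genome that differ between the 2 lines, from other induced mutations or from another strain, would be consistent with 20 clustered genes and 0 random sets as many, but the sequence of the lines was not used here, and an effect of Disc1 on these genes was not tested apart from it.

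Labelled sex and the sex-linked genes differ on many arrays. Eif2s3y, expressed in male cells only, fell into a low set (up to 6.00) and a high set (from 8.05), and Xist was above the limit of 7 on 27 of the low arrays and 0 of the high ones. On 43 of 69 arrays the set was not that of the label: 9 of 16 in brain stem, 8 of 17 in frontal cortex, 12 of 19 in hippocampus and 14 of 17 in striatum. In 12 of 16 groups the number of Eif2s3y-high arrays nevertheless equals the number labelled male, and in 0 of the 4 groups of mutants on valproate. The groups are those of the labels throughout, and neither sex was compared with the other.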
